A study of Mus musculus with 3 samples.

How the data were processed

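Total RNA depleted of ribosomal RNA was sequenced from the cytosolic fraction of C57BL/6J mouse bone-marrow-derived macrophages, 3 libraries of 1 condition (100 ng/ml Lipid A, 20 min), per the labels. The labels number them as biological replicates but give all 3 the same donor identifier. SDs therefore measure the spread between these samples, part of which may be technical. The p-values rank a list of genes against random lists of genes and do not measure that spread. The group of each library and its replicate number were taken from the labels. Strandedness of the libraries is not given in the sources used here, so reads of overlapping antisense genes could not be told apart.

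Each library came with a gene table, a transcript table and a second transcript table. Per the file headers and the notes deposited with each library, the gene table and first transcript table were derived from alignments to the transcriptome, and the second transcript table directly from the reads, all on mm10 with the GENCODE M21 annotation. Their column names are those that RSEM and kallisto write; the tools and their versions are not given in the sources used here. The deposited expected counts are estimates of reads per gene and need not be whole. The deposited TPM values are scaled to 1 fixed sum over all rows of each library, and the deposited FPKM values are fragments per kilobase of transcript at a common depth. The gene table also carried a posterior mean TPM and interval bounds, whose level is not given; the bounds were not used in any test. Because TPM has a fixed sum, abundant short RNAs lower the TPM of every mRNA, and a different content of them between libraries shifts all mRNAs together. Reads of near-identical genes are split by the estimate.

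The gene table had 55536 gene rows, all with a symbol in M21. Rows that name no gene stayed out of library sizes and tests: 26248 rows with a numeric identifier held 2, 1 and 3 counts in replicates 1, 2 and 3, 96 ERCC spike-in rows held 0, and 1 phiX174 row held 0.402%, 0.108% and 0.122% of the counts. Totals of gene rows after rounding were 27282449, 81509879 and 37131767. A gene with few counts carries a counting error of a large part of its value.

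Before the data were examined, 28 gene lists with 362 symbols were fixed, together with the tests, the alternatives and the rule for naming genes. The rule named the 10 genes of highest mean TPM, a fixed set of response, receptor and macrophage genes, the 3 highest members of each other list, and the 10 genes with the largest SD of log2(TPM + 1) at a mean of at least 10 TPM. Other genes are named as exceptions to a count or as examples of a list, and were chosen after their values were seen. The values of 3 genes that these choices would name are not reported here. All symbols but Norad matched. Where a symbol had 2 identifiers (Rmrp, Ddit3, Aldoa), list values used the one with the higher mean. A gene was called detected at 1 TPM or more in all 3 libraries. A list's level is the median over members of the mean TPM. Early and late lists were compared by the difference of their median log2(TPM + 0.1) within a library. With 1 condition, no test between groups was possible.

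Spread between libraries was the median SD of log2(TPM + 1) of a list's members with a mean of at least 1 TPM, for the 16 lists with 5 or more such members. It was set against 10000 random lists, each member replaced by 1 of the 200 genes nearest in mean expression. Two-sided p-values were adjusted by Benjamini-Hochberg over the lists. They are called permutation p-values below, although they come from drawing random genes and no library labels were permuted. The share of a gene's TPM in transcripts of the M21 biotype retained_intron was tested the same way over protein-coding genes. A further match on GC content and transcript length drew from the 100 genes nearest in both among 1000 of like expression. For the spread of counts, expected counts were rounded to whole numbers, filtered with filterByExpr at a minimum count of 10, normalised by TMM and given to edgeR's estimateDisp with an intercept only; TMM factors were 1.04, 0.991 and 0.975. DESeq2 was run as an alternative.

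Alternatives were leaving out each library, other detection limits and pseudocounts, FPKM, posterior mean TPM, the second transcript table summed to genes, TPM rescaled over nuclear-encoded protein-coding genes, TMM-normalised log2 CPM with a prior count of 2, a minimum mean of 5 TPM, and other normalisations and filters for the coefficient of variation. The second table after rescaling was added as an alternative after the data were seen.

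Both procedures were tested on simulated data. Counts drawn for the real genes with coefficients of variation of 0.1, 0.2 and 0.4 returned 0.0991, 0.198 and 0.394. For the spread test, counts of 9730 genes were simulated with 200 genes set 2 times higher in 1 library. Of 50 lists of 15 such genes 100% were recovered, and of 200 lists of unchanged genes 4.5% were called at an unadjusted p below 0.05. The lists of unchanged genes held no planted shared shift, so the 4.5% does not cover lists whose genes move together. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.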

Results

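RNA from the cytosolic fraction of mouse bone-marrow-derived macrophages was sequenced after 20 min of stimulation with Lipid A at 100 ng/ml. Macrophages of this kind are grown from marrow precursors in culture, and Lipid A is the part of bacterial lipopolysaccharide that the receptor Tlr4 recognises. The cells came from the C57BL/6J strain, and ribosomal RNA was depleted before sequencing. The labels give 3 libraries of this 1 condition, numbered as biological replicates 1 to 3. Unstimulated cells, other times and the nuclear fraction are not analysed here, so the text gives levels and their spread and says of no gene that it was induced or repressed. The deposited gene tables held 27392626, 81597761 and 37176950 expected counts in replicates 1, 2 and 3. A count of 3, the limit that a count of 0 allows, is 0.110, 0.0368 and 0.0807 CPM in the same order, which covers counting error only.

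Small structural RNAs took most of the transcript abundance in the gene table. The 7SL RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, together held 63.4% ± 1.66 of all TPM (SD, n = 3) and 11.3% ± 1.95 of expected counts. Rn7s2 stood at 318557 ± 8188 TPM and Rn7s1 at 315147 ± 8525 TPM. Both are annotated on chromosome 12 of mm10, at 69361182 to 69361481 and 69159295 to 69159594. They are near-identical copies, so the split between them is uncertain. In the second transcript table Rn7s1 and Rn7s2 stood at 98208 TPM each. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, followed at 63571 ± 7042 TPM, then Rpph1, the RNA of ribonuclease P, at 38386 ± 4338 TPM. Rmrp, the RNA of ribonuclease MRP, is annotated under 2 identifiers, with 13004 ± 1647 and 5969 ± 514 TPM. The highest protein-coding genes were Ftl1 (8552 ± 447 TPM) and Fth1 (7310 ± 1115 TPM), the ferritin chains that store iron. Lyz2, a lysozyme of myeloid cells, and Psap, a lysosomal activator precursor, followed at 4579 ± 1025 and 4409 ± 111 TPM. These are the 10 highest genes, Rmrp counted under each identifier (SD, n = 3 throughout).

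Nuclear-encoded protein-coding genes held 84.0% ± 2.93 of expected counts but 22.2% ± 2.67 of TPM. Their share of TPM was 25.0%, 22.0% and 19.6% in replicates 1, 2 and 3. TPM of an mRNA therefore rests on the small-RNA content of its library, and levels between libraries are also given after rescaling TPM over the nuclear-encoded protein-coding genes. The 50 genes with the most counts held 33.5% ± 2.58 of counts. Ribosomal protein genes held 1.83% ± 0.262 of counts, mitochondrially encoded mRNAs 0.664% ± 0.297 and replication-dependent histone genes 0.0692% ± 0.0118. In all 3 libraries 9346 genes reached 1 TPM, of which 8928 were protein-coding, 59 lincRNAs and 47 antisense genes. The separate libraries had 9844, 9676 and 9548 such genes.

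**Figure D1:**
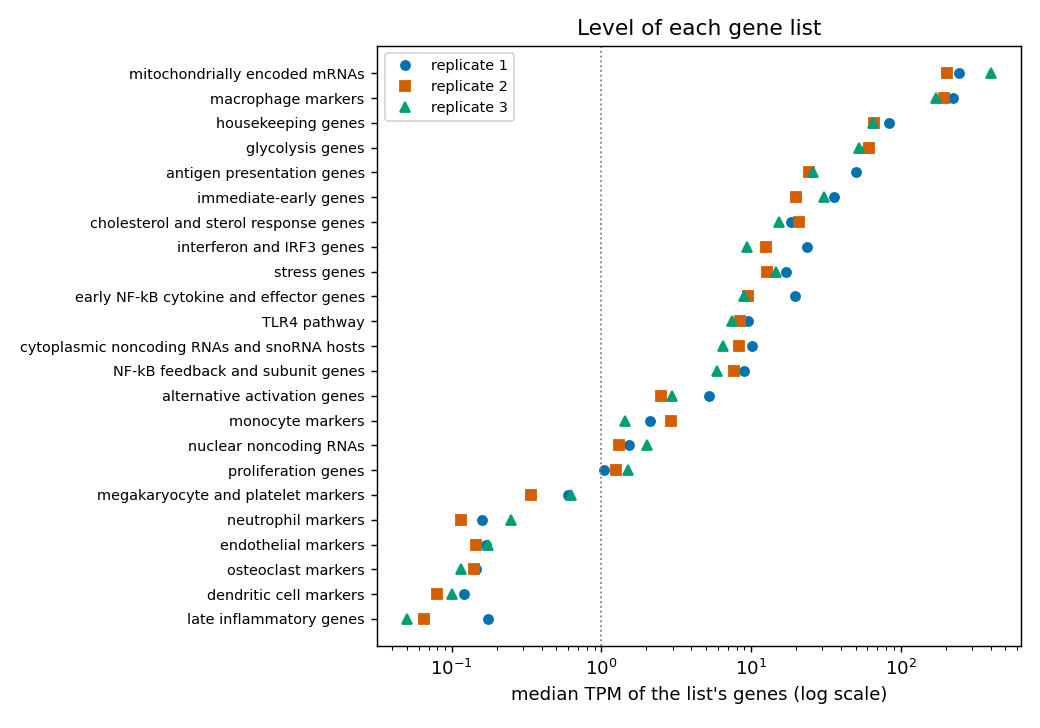
Median TPM of each fixed gene list in each library (log axis); circles, squares and triangles are replicates 1, 2 and 3, and the dotted line marks 1 TPM. The 23 lists with a median above 0 in every library are drawn; macrophage markers lie near 200 TPM and late inflammatory genes near 0.1 TPM.

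Immediate-early genes, which are transcribed without new protein synthesis after a stimulus, were abundant in the RNA of the cytosolic fraction. The nuclear noncoding RNA Malat1 averaged 457 TPM in the same fraction. How much of the immediate-early RNA came from carryover of nuclear RNA was not tested. Of 29 measured members, 26 reached 1 TPM in all 3 libraries, and the list's median stood at 31.9 TPM, above 88.2% of the genes with a mean of at least 1 TPM. Zfp36, which encodes the mRNA-destabilising protein tristetraprolin, was the highest by mean TPM at 228 ± 50.1 TPM (SD, n = 3), with 34491, 73852 and 40765 expected counts. Fos, a subunit of the AP-1 transcription factor, stood at 226 ± 45.4 TPM, Junb at 151 ± 22.6 and Jun at 71.6 ± 18.9. After rescaling over protein-coding genes Fos was above Zfp36, at 1034 against 1024 TPM. Atf3, a stress-responsive transcription factor, stood at 88.4 ± 13.0 TPM and the MAP kinase phosphatase Dusp1 at 67.7 ± 14.4. Ier2 stood at 97.6 ± 38.0 TPM. Other members were low or differed between libraries: Fosb at 6.47 ± 3.45 TPM, Egr2 at 9.05 ± 4.88, and Fosl1 with 1.02 expected counts in replicate 2 and 0 in the others. Egr1, a zinc-finger transcription factor at 34859823 to 34864984 on chromosome 18, was at 137, 36.7 and 123 TPM in replicates 1, 2 and 3. After rescaling it was at 550, 167 and 626 TPM, so which of replicates 1 and 3 was highest depended on the scale.

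Genes for early NF-kB cytokines and effectors were present at a median of 12.8 TPM, and 15 of 18 reached 1 TPM in all libraries. The chemokine genes Ccl3 and Ccl4 were the highest, at 135 ± 51.1 and 111 ± 43.9 TPM (SD, n = 3). Tnf, the gene of tumour necrosis factor at 35199381 to 35202007 on chromosome 17, averaged 81.8 ± 72.6 TPM from 11776, 8228 and 5036 expected counts, or 165, 34.97 and 45.0 TPM. The neutrophil-attracting chemokines Cxcl2 and Cxcl1 stood at 37.7 ± 25.1 and 9.32 ± 8.19 TPM and Il1b at 17.6 ± 15.1 TPM. After rescaling over protein-coding genes, Tnf was at 662, 159 and 229 TPM in replicates 1, 2 and 3, so its difference between libraries remained. Cxcl3, Il23a and Lif were below 1 TPM in all 3 libraries, with at most 6 expected counts each in any library.

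The NF-kB feedback and subunit genes, which include the inhibitors made in response to the pathway, had a median of 7.77 TPM, and 18 of 19 reached 1 TPM in all libraries. Nfkbia, which encodes the inhibitor IκBα at 55489410 to 55492647 on chromosome 12, was the highest at 103 ± 70.0 TPM (SD, n = 3), with 182, 73.9 and 51.3 TPM in replicates 1, 2 and 3. Ier3 stood at 89.5 ± 36.4 TPM and Tnfaip3, the gene of the deubiquitinase A20, at 16.4 ± 9.76 TPM. Among the subunit genes, Nfkb1 stood at 15.5 ± 2.74 and Rel at 6.34 ± 1.44 TPM.

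**Figure D2:**
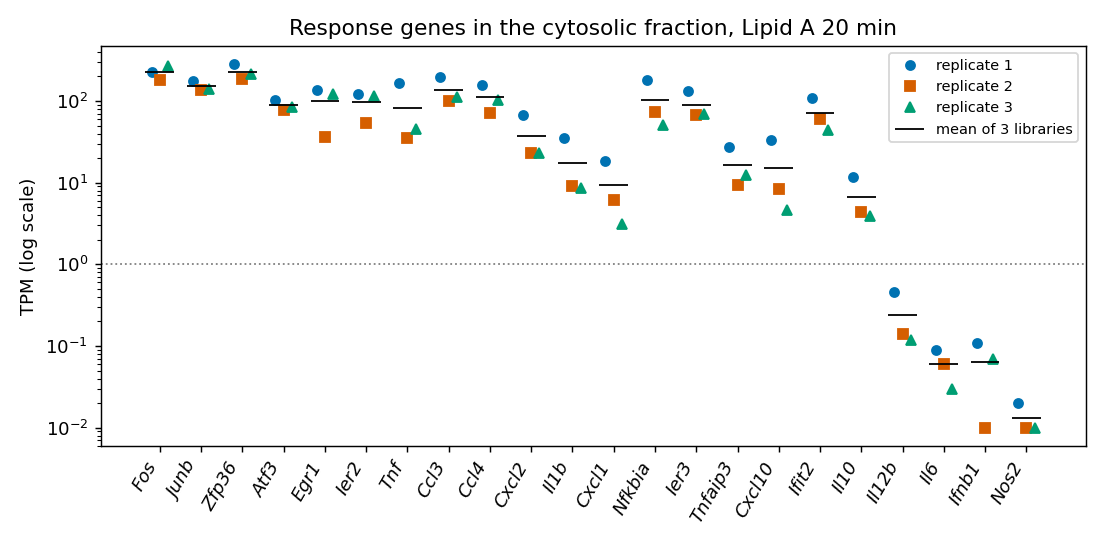
TPM (log axis) of response genes in each library; symbols are replicates 1 to 3, the horizontal bars their mean and the dotted line 1 TPM. Fos and Zfp36 lie above 179 TPM in every library, and Il6, Il12b, Ifnb1 and Nos2 below 0.5 TPM.

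Late inflammatory genes, many of which need new protein synthesis or chromatin opening, were mostly below 1 TPM. Of 14 members, 11 were below 1 TPM in all 3 libraries, or 7 after rescaling over protein-coding genes, and the list's median was 0.0983 TPM, or 0.0625 TPM without replicate 1. Il6 had 6, 7 and 1 expected counts (0.0600 ± 0.0300 TPM, SD, n = 3), Nos2, the inducible nitric oxide synthase, 5, 7 and 3 counts, and Il12b 38, 37 and 16 counts (0.240 ± 0.191 TPM). Il12a, Csf3 and Il33 had 0 counts in every library and were not detectable at this depth. Saa3, an acute-phase protein gene (9.99 ± 5.28 TPM), and Acod1, which makes itaconate (2.96 ± 2.36 TPM), were the members that reached 1 TPM in all libraries. Lcn2 averaged 1.07 ± 0.116 TPM.

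Interferon and IRF3 genes were present at a median of 15.8 TPM, and 22 of 23 reached 1 TPM in every library. The exception was Ifnb1, the interferon-β gene itself, with 3, 1 and 3 expected counts. Ifit2 and Ifit3 were the highest, at 70.5 ± 32.9 and 63.8 ± 23.7 TPM (SD, n = 3). Cxcl10, a chemokine gene shared by the interferon and NF-kB responses, was at 33.1, 8.26 and 4.61 TPM in replicates 1, 2 and 3.

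The order of early and late response genes was compared within each library. The median log2(TPM + 0.1) of the early NF-kB genes exceeded that of the late inflammatory genes by 6.23, 5.88 and 5.92 in replicates 1, 2 and 3 (mean 6.01 ± 0.19, SD, n = 3). For immediate-early genes against late inflammatory genes the difference was 7.24 ± 0.40. Immediate-early genes exceeded interferon genes by 0.60, 0.66 and 1.70, a mean of 0.99 ± 0.62, which is wide against its size and was 0.63 without replicate 3. All 9 differences were positive, but 3 libraries cannot pass an exact sign-flip test, whose smallest two-sided p is 0.25, and these differences of levels between genes say nothing of a change over time. The size of the first 2 contrasts follows the pseudocount: with a pseudocount of 1 they were 3.57 and 4.73.

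The Lipid A receptor complex and its signalling chain were expressed, with 24 of 25 TLR4 pathway genes at 1 TPM or more in all libraries and a median of 8.57 TPM. The co-receptor gene Cd14 was at 100.2 ± 26.6 TPM (SD, n = 3), Tlr4 at 26.8 ± 3.88, Ly96, which encodes the Lipid A-binding protein MD-2, at 13.8 ± 3.27 and the kinase adaptor Tab2 at 21.8 ± 3.41 TPM. Lbp, made mainly by liver, was the exception at 0.417 ± 0.0929 TPM. Macrophage markers had a median of 205 TPM, and 33 of 34 reached 1 TPM in all libraries. Beside Lyz2, the lysosomal proteases Ctsd and Ctsb were at 3750 ± 184 and 2274 ± 198 TPM. Csf1r, the growth factor receptor of macrophages, was at 214 ± 41.3 TPM and Adgre1, the gene of the F4/80 antigen, at 139 ± 20.1 TPM. Cx3cr1 was the member below 1 TPM (0.137 ± 0.0351).

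Markers of other blood and tissue cells were low, with few exceptions. All members of the dendritic cell (Ccr7 highest, 0.473 ± 0.0666 TPM), T and NK cell (Lck, 0.0867 ± 0.0666), mast cell and basophil (Mcpt8, 0.0833 ± 0.0839), erythroid (Alas2, 0.0367 ± 0.0351) and fibroblast lists (Col1a1, 0.0267 ± 0.0208) were below 1 TPM in all 3 libraries. After rescaling over protein-coding genes Ccr7 was above 1 in every library and Siglech in replicates 2 and 3, while the other 4 of these lists stayed below 1 throughout. Next to these highest members came Siglech (0.20 ± 0.070) and Clec9a (0.133 ± 0.0757), Cd3e (0.0400 ± 0.0693) and Klrb1c (0.0233 ± 0.0231), Cpa3 (0.030 ± 0.010) and Ms4a2 (0.0167 ± 0.0208), Hba-a1 (0.010 ± 0.0173), and Cxcl12, Col1a2 and Dcn at 0.0200, 0.0133 and 0.0133 TPM. Of the B cell markers, Cd79b stood at 0.743 ± 0.223 TPM and the next, Jchain and Cd79a, at 0.0600 ± 0.0265 and 0.0233 ± 0.0153. Among neutrophil markers S100a9 (13.1 ± 2.17 TPM), S100a8 (8.65 ± 2.15) and Ngp (1.94 ± 0.805) reached 1 TPM in every library, while Ly6g had 0, 0 and 1 counts. The platelet factor gene Pf4 was at 163 ± 18.9 TPM, whereas the other megakaryocyte markers Ppbp and Itga2b were at 0.873 ± 0.270 and 0.173 ± 0.0874. Kdr reached 2.36 ± 1.02 TPM while the endothelial genes Cdh5 and Pecam1 were both at 0.163 TPM. The monocyte markers Ccr2 and Ly6c2 were at 3.26 ± 0.331 and 2.17 ± 0.751 TPM. The osteoclast genes Acp5 and Ctsk were at 1.28 ± 0.467 and 0.970 ± 0.199 TPM, with Dcstamp at 0.167 ± 0.0611 (SD, n = 3 throughout).

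Metabolic and housekeeping genes gave the background level of the cells. All 14 glycolysis genes reached 1 TPM in every library (median 57.7 TPM), led by Aldoa at 154 ± 21.5, Pkm at 109 ± 7.85 and Ldha at 102 ± 8.51 TPM. All 10 cholesterol and sterol response genes did so too (median 18.1 TPM), led by the cholesterol exporters Abca1 and Abcg1 at 93.6 ± 7.48 and 46.0 ± 1.11 TPM and by Hmgcs1 at 27.3 ± 3.62. The 13 housekeeping genes had a median of 71.5 TPM, with Actb at 1783 ± 170, Eef1a1 at 1467 ± 260 and Ppia at 394 ± 60.8. Of the stress genes, 12 of 16 passed, led by Hspa8 at 367 ± 89.8, the autophagy receptor Sqstm1 at 123 ± 11.5 and the heme oxygenase Hmox1 at 98.2 ± 9.51 TPM. Of the proliferation genes 10 of 19 passed with a median of 1.25 TPM, and all 19 did after rescaling. On the TPM scale Pcna stood at 62.9 ± 4.27 before Mcm3 at 5.78 ± 0.599 and Cdk1 at 5.30 ± 0.227. Of the antigen presentation genes 11 of 12 passed, led by B2m at 1578 ± 354, H2-D1 at 1011 ± 129 and H2-K1 at 660 ± 114 TPM. Of 9 alternative activation genes 5 passed, Il4ra at 18.1 ± 2.40, Clec10a at 9.70 ± 2.499, Il10 at 6.72 ± 4.49, Folr2 and Chil3, while Retnla had no counts (SD, n = 3 throughout).

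Nuclear and mitochondrial RNAs were measured as markers of other compartments. Malat1, a noncoding RNA retained in nuclear speckles, was at 359, 248 and 763 TPM in replicates 1, 2 and 3, and the paraspeckle RNA Neat1 at 31.7, 23.6 and 83.9 TPM. The highest of the 11 nuclear noncoding RNAs was Rn7sk, at 63571 ± 7042 TPM or 6.36% of all TPM. Of the 11, 6 reached 1 TPM in all libraries. All 13 mitochondrially encoded mRNAs did, with a median of 278 TPM. Among them mt-Atp8 was at 1817 ± 721, mt-Co1 at 1070 ± 407 and mt-Nd1 at 386 ± 166 TPM (SD, n = 3). The open reading frames of mt-Atp8 and mt-Atp6 overlap, and the split of their reads is uncertain. Of the 13 measured members of the list named cytoplasmic noncoding RNAs and snoRNA hosts, 10 reached 1 TPM in all libraries, among them Gas5 at 28.9 ± 5.56 TPM. This list also held Rpph1 and Rmrp, and its name does not give the location of each member. Rny1 and Rny3 had 0 counts in every library.

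The spread between libraries exceeded that of matched genes for 8 of the 16 lists tested, among them the early NF-kB and interferon genes. The median SD of log2(TPM + 1) over libraries was 0.58 for the early NF-kB genes, against 0.18 for random lists matched on mean expression. It was 0.51 against 0.18 for interferon genes, 0.39 against 0.17 for NF-kB feedback genes and 0.33 against 0.18 for immediate-early genes. Each lay above all of 10000 random lists (unadjusted p = 0.0002 from this permutation, the smallest it can give; adjusted p = 0.00064 over 16 lists). Mitochondrially encoded mRNAs gave 0.55 against 0.26 (permutation, adjusted p = 0.00064), nuclear noncoding RNAs 0.55 against 0.18 (0.0011), alternative activation genes 0.33 against 0.16 (0.0059) and antigen presentation genes 0.34 against 0.20 (0.0084). The other 8 lists did not pass: TLR4 pathway, 0.19 against 0.17; macrophage markers, 0.20 against 0.23; proliferation, 0.16 against 0.14; stress, 0.15 against 0.18; glycolysis, 0.15 against 0.19; cholesterol, 0.19 against 0.18; housekeeping, 0.19 against 0.22; cytoplasmic noncoding RNAs, 0.20 against 0.19. Genes are not replicates and co-regulated genes move together, so these values describe the 3 libraries.

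Single libraries carried several of these calls. Without replicate 2 the immediate-early genes differed from matched lists by 0.021 (permutation, adjusted p = 0.559). Without replicate 1 the NF-kB feedback genes differed by 0.051 (0.109), alternative activation genes by 0.010 (0.885) and antigen presentation genes by -2.34e-05 (0.999), and the last differed by 0.086 without replicate 3 (0.0632). Without replicate 3 nuclear noncoding RNAs differed by 0.10 (0.102) and mitochondrially encoded mRNAs by 0.040 (0.311). The early NF-kB difference went from 0.40 to 0.13 without replicate 1 and kept its call (0.0024), and the interferon genes kept theirs without any 1 library. After rescaling over protein-coding genes the alternative activation list did not pass (0.078, 0.160) while the proliferation (0.27, 0.00057) and cholesterol lists (0.082, 0.0215) did. After TMM the proliferation (0.25, 0.00046), cholesterol (0.11, 0.0032) and cytoplasmic noncoding lists (0.19, 0.0028) passed. In the second transcript table mitochondrially encoded mRNAs did not pass (0.025, 0.726), nor did alternative activation genes (0.052, 0.357), and proliferation genes lay below matched lists (-0.098, 0.0045). In that table after rescaling, antigen presentation (0.063, 0.155) and alternative activation genes (0.13, 0.0899) did not pass, and proliferation (0.19, 0.0199) and cholesterol genes (0.088, 0.0204) did. Macrophage markers lay below matched lists without replicate 1 (-0.090, 0.0160) or 2 (-0.069, 0.0292), glycolysis genes did so without replicate 3 (-0.074, 0.0453) or at a minimum of 5 TPM (-0.058, 0.0457), and cholesterol genes lay above them without replicate 1 (0.13, 0.0160). Under the other alternatives that gave a value, adjusted p by permutation was at most 0.0225 for immediate-early, 0.0010 for NF-kB feedback, 0.0181 for nuclear noncoding and 0.0011 for mitochondrial RNAs.

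The direction of these deviations was examined after the spread had been seen, and it was read after rescaling, since the median gene at 1 TPM or more deviated by 0.14, -0.01 and -0.13 log2 units in replicates 1, 2 and 3 on the TPM scale and by -0.01, 0.00 and 0.01 after it. Early NF-kB genes were highest in replicate 1 for 14 of 15 members (15 on the TPM scale), with a median deviation of 0.53 from their own mean, against -0.39 and -0.26 in replicates 2 and 3. Interferon genes were highest in replicate 1 for 22 of 22 members and lowest in replicate 3 for 20. NF-kB feedback genes were highest in replicate 1 for 18 of 19. Immediate-early genes were lowest in replicate 2 for 21 of 26, with 15 highest in replicate 3 and 11 in replicate 1. On the TPM scale 20 of these 26 were highest in replicate 1. Proliferation genes were lowest in replicate 1 for 11 of 12 members. Nuclear noncoding RNAs were highest in replicate 3 for 5 of 6 members (median deviation 0.88; the exception was Terc), and mitochondrially encoded mRNAs for 12 of 13 (0.78; the exception was mt-Co3).

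**Figure D3:**
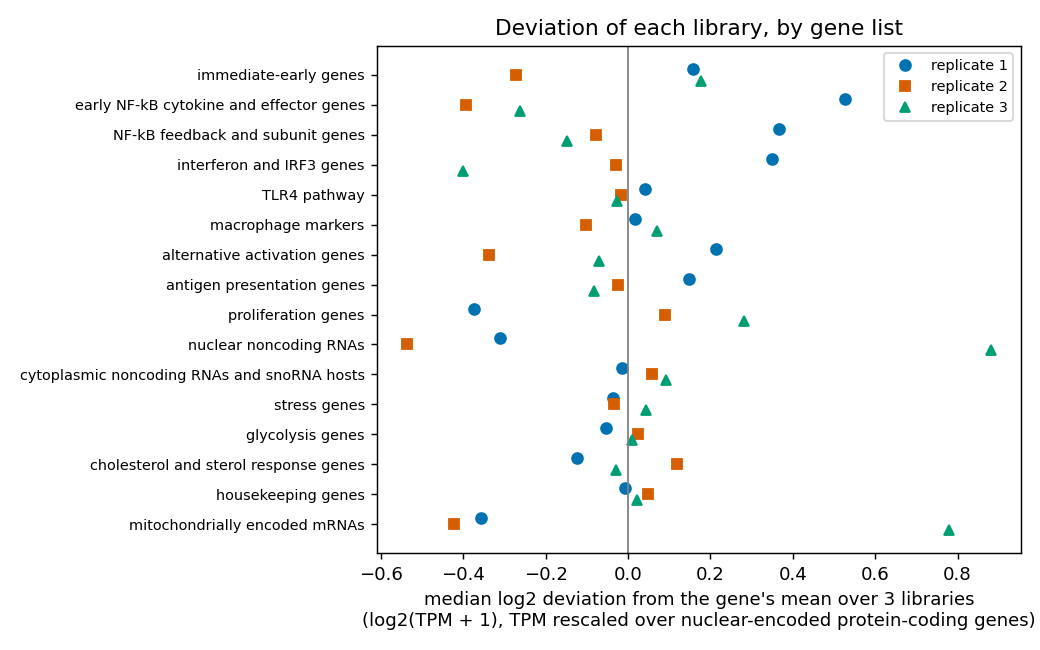
Median log2 deviation of each list's members from their own mean over 3 libraries, after rescaling TPM over nuclear-encoded protein-coding genes; circles, squares and triangles are replicates 1, 2 and 3. Early NF-kB genes deviate by 0.53 in replicate 1, and nuclear noncoding RNAs and mitochondrially encoded mRNAs by 0.88 and 0.78 in replicate 3.

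The genes of largest SD between libraries at a mean of at least 10 TPM were mostly short noncoding genes with few reads. They were the snRNA genes Gm24924 and Gm24497, Rnu3a under 2 overlapping identifiers, Gm44313, the pseudogene Gm14303, Gm20721 and the ribosomal RNA gene CT010467.1, and then Cxcl10 and the cytokine signalling inhibitor Socs3 (10.5 ± 9.48 TPM, SD, n = 3). Gm24924 had 0, 264 and 0.0600 expected counts in replicates 1, 2 and 3. The measure that edgeR names the biological coefficient of variation was 0.130 over the 12430 genes that passed the count filter. Without that filter it was 0.144 over 22129 genes. Part of it may be technical, since the libraries share 1 donor identifier.

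The share of transcripts annotated with a retained intron passed the adjusted test in no list; 3 of 12 lists had an unadjusted permutation p below 0.05. The median share of a gene's TPM in such transcripts was 12.2% for 8 early NF-kB genes against 1.57% for matched lists, and 11.4% for 9 immediate-early genes against 1.505% (permutation, adjusted p = 0.0768 for both over 12 lists). In the second transcript quantification both passed (permutation, adjusted p = 0.0286 and 0.0308), as did the TLR4 pathway (0.0286). The shares of Cxcl2 were 12.1%, 17.0% and 33.8% in replicates 1, 2 and 3, those of Il1b 11.1%, 18.3% and 29.1%, and those of Tnfaip3 18.1%, 16.3% and 34.6%. Among the early NF-kB genes, Icam1 (8.06%, 4.66% and 7.72%) and Csf1 (1.595%, 0.985% and 0.739%) were highest in replicate 1 instead. The other early NF-kB genes with such transcripts were highest in replicate 3. So were 68.9% of the 5515 genes with a share above 0 in any library, so this was not particular to the list. For Cd83, an activation marker, the share was 76.0% ± 1.56 (SD, n = 3). NF-kB feedback genes (2.25% against 2.12%) and interferon genes (1.62% against 1.61%) lay near their matched lists. The remaining lists had adjusted p between 0.123 and 0.985 by the same permutation. Short reads assign isoforms with error, and these shares are the deposited estimates.

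Libraries and quantifications were correlated across genes. Pearson's r of log2(TPM + 1) across 55536 genes was 0.995 for replicates 1 and 2, 0.993 for 1 and 3 and 0.995 for 2 and 3, with Spearman's rho of 0.924, 0.922 and 0.928. Between the gene table and the second transcript table summed to genes, r was 0.963, 0.964 and 0.950 and rho 0.850, 0.842 and 0.828 in replicates 1, 2 and 3. Genes are not independent replicates, and no p is given. Of 256 list genes at 1 TPM or more, 241 were over 2 times lower in the second table, where protein-coding genes held 8.72% of TPM. After scaling to the protein-coding total, 4 remained over 2 times apart, among them mt-Co2 and mt-Atp6, which were higher, and mt-Atp8, which was lower in the second table.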

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

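PhiX174, the bacteriophage whose DNA is used as a sequencing control, had counts in every library in a row outside the comparisons. It held 110180, 87871 and 45173 expected counts in replicates 1, 2 and 3, or 0.402% (95% Wilson interval 0.3999 to 0.405), 0.108% (0.107 to 0.108) and 0.122% (0.120 to 0.123) of all counts, far above the 3 counts that a count of 0 allows. These intervals and this limit cover counting error only. The second transcript table gave 121894, 100944 and 50959. The ERCC spike-in rows held 0 counts in the gene table and 0, 7 and 11 in the second transcript table.

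In the second transcript table, 146 genes at a mean of 1 TPM or more had no counts in any library of the gene table, and they held 67.1% ± 4.68 of that table's TPM (SD, n = 3). Of this, 5 genes held 67.0%: the processed pseudogenes Gm12895 and Gm12896 on chromosome 4, and the miRNA-biotype genes Gm23935, Gm24270 and Gm24245. Their share was 63.6%, 65.0% and 72.3% of TPM in replicates 1, 2 and 3.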

How the results depend on the processing

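TPM levels of the lists depended on the processing, and the sign of the early minus late differences did not. Rescaling the second table was chosen after the data were seen. The number of detected genes stayed between 7248 (second table) and 12394 (10 counts in all libraries). List medians moved with the scale, by construction. In the second table immediate-early genes stood at 14.3 TPM, early NF-kB genes at 5.19, NF-kB feedback genes at 3.66, interferon genes at 6.11, macrophage markers at 83.0, nuclear noncoding RNAs at 0.827 and mitochondrially encoded mRNAs at 126. After rescaling over protein-coding genes the same lists stood at 144, 56.8, 34.8, 69.5, 917, 8.57 and 1298 TPM and late inflammatory genes at 0.427. In FPKM they stood at 63.4, 25.2, 15.4, 31.0, 406, 3.71 and 563, with late genes at 0.190. The late genes' posterior mean TPM was 0.223. Leaving out 1 library gave 22.5 to 33.4 TPM for immediate-early, 6.08 to 8.68 for NF-kB feedback, 1.43 to 2.10 for nuclear noncoding RNAs and 0.0625 to 0.117 for late genes.

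Early NF-kB minus late inflammatory genes was 4.96 log2 units in the second table, 6.85 after rescaling, 3.57 and 7.04 with pseudocounts of 1 and 0.01 and 4.90 over members at 0.1 TPM or more. Immediate-early minus late genes was 6.27, 8.08, 4.73, 8.27 and 5.85. Neither the second table nor the limit of 0.1 TPM changed the sign of either. The other alternatives could not test it. Rescaling and the pseudocount keep the order of genes within a library, and every single library had positive differences. The top 50 genes held 82.3% of TPM and 23.8% of protein-coding counts. The coefficient of variation was 0.106 with DESeq2, taken from the median of the dispersions of single genes. The like value from edgeR was 0.104, while the 0.130 given above comes from its common dispersion. Correlations of log2(TPM + 0.1) over genes at a mean of 1 TPM or more averaged 0.968 between libraries and 0.946 between quantifications. Both the pseudocount and the set of genes differ from the main values.

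Spread is given as the list's value minus that of matched lists. In the second table proliferation genes stood at -0.098, past the threshold, and mitochondrially encoded mRNAs at 0.025 and alternative activation genes at 0.052, which did not pass. Rescaled, the second table gave 0.51 for mitochondrially encoded mRNAs, 0.19 for proliferation and 0.088 for cholesterol, which passed, and 0.13 for alternative activation, 0.063 for antigen presentation, 0.027 for stress and -0.0041 for the TLR4 pathway, which did not. Rescaling the gene table gave 0.27 for proliferation and 0.082 for cholesterol, which passed, and 0.078 for alternative activation, 0.019 for stress and -0.0067 for the TLR4 pathway, which did not. TMM gave 0.25 for proliferation, 0.11 for cholesterol and 0.19 for cytoplasmic noncoding RNAs, which passed, and 0.043 for stress and -0.0021 for the TLR4 pathway, which did not. At a minimum of 5 TPM cytoplasmic noncoding RNAs stood at -0.011 and glycolysis, which passed, at -0.058. Leaving out 1 library gave 0.021 to 0.28 for immediate-early, 0.051 to 0.29 for NF-kB feedback, 0.040 to 0.55 for mitochondrially encoded mRNAs, 0.10 to 0.63 for nuclear noncoding RNAs, 0.010 to 0.24 for alternative activation and -2.34e-05 to 0.16 for antigen presentation. It gave -0.090 to 0.023 for macrophage markers, -0.019 to 0.047 for proliferation, -0.083 to 0.029 for stress, -0.074 to -0.0076 for glycolysis, -0.081 to 0.13 for cholesterol and -0.045 to 0.073 for cytoplasmic noncoding RNAs. Early NF-kB and interferon genes passed under every alternative run. Beyond fewer libraries or genes and the change of scale, the cause of these moves was not tested. Lists with under 5 members left at a stricter limit or in the second table gave no value.

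Retained-intron shares minus matched lists were 10.4 percentage points for immediate-early, 13.4 for early NF-kB and 5.89 for TLR4 pathway genes in the second table, all past the threshold. Interferon genes stood at -0.140 at a minimum of 5 TPM. Leaving out 1 library gave -0.358 to 0.471 for interferon, -0.519 to 2.26 for proliferation and -0.128 to 0.759 for NF-kB feedback genes. At this depth Il6 and Nos2 rest on at most 7 counts in a library, and 4 erythroid, 3 T and NK cell and 3 mast cell markers had no counts.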

Other observations

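Sex-linked transcripts could be read although the labels record no sex. The Y-linked genes Ddx3y, Eif2s3y and Uty had 0 counts in all 3 libraries and Kdm5d had 1, 0 and 0, while Xist, the noncoding RNA of the inactive X chromosome, had 2513, 3338 and 6542 expected counts in replicates 1, 2 and 3. The small nucleolar RNA gene Rnu3a is annotated under 2 identifiers from position 40258467 on chromosome 10. All its reads fell on 1 identifier in replicate 1 (39 counts against 0) and on the other in replicates 2 and 3 (120 and 79 against 0), so neither identifier alone gives its level. The ribosomal RNA gene CT010467.1 had 8687, 3423 and 7909 counts.

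The patterns weighed here were seen before they were tested. For early NF-kB genes, the tests of rescaling and of nuclear RNA were chosen only after the values they measure had been seen, as were the comparison of mitochondrial ribosomal RNAs with replicate 1 alone and the bound on the match (5 points of GC content, 1.2 times in length); the others were set beforehand. The design names no difference between the libraries, so no biological explanation was tested.

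Early NF-kB genes were highest in replicate 1. Against 10000 lists matched on expression, GC content (46.3% against 49.2% in the drawn genes) and length, their median deviation in replicate 1 lay at percentile 100, which argues against a bias of GC content or length as the whole cause. After rescaling over protein-coding genes the median deviation was 0.53, against 0.65 before, which argues against a shift of the TPM scale by small RNAs as the whole cause. After rescaling, nuclear noncoding RNAs differed by -1.11 log2 units at the median between replicates 1 and 3 (5 of 6 lower in replicate 1) where early NF-kB genes differed by 0.54, which argues against carryover of nuclear RNA for that difference. Between replicates 1 and 2 they differed by 0.17 (5 of 6 higher in replicate 1) and early NF-kB genes by 0.90, so a part from carryover stays open there.

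Nuclear noncoding RNAs were highest in replicate 3. Carryover of nuclear RNA predicts more intron-containing isoforms there, and 68.9% of the 5515 genes with a share above 0 in any library had their highest share in replicate 3, against 33% by chance; the second transcript table gave 73.0%. This is consistent with more nuclear RNA in replicate 3, as a hypothesis. The list lay at percentile 100 of lists matched on GC content and length, but the drawn genes were shorter (4913 against 6269 bases at the median), so a bias of length stays open. Less efficient splicing or a difference in isoform assignment was not tested.

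Mitochondrially encoded mRNAs were also highest in replicate 3. Their list lay at percentile 100 of matched lists, but the match was incomplete (37.1% GC against 43.3% in the drawn genes, and 784 against 1323 bases). The 100 genes nearest in GC content and length were within the bound on GC content (40.4%) but not on length (1034 bases). They deviated by -0.03 in replicate 3 after rescaling, where the mitochondrial list deviated by 0.78. This argues against GC content alone as the whole cause. A bias of length, alone or with GC content, stays open. Carryover of mitochondria should raise their ribosomal RNAs too, and the smaller of the ratios of these, replicate 3 over the mean of the others, was 1.63 and the larger 1.99, past the bound set beforehand. In replicates 1 and 3 mt-Rnr1 stood at 11.2 and 11.3 TPM and mt-Rnr2 at 5.42 and 6.55 TPM, or 44.8 and 57.5, and 21.7 and 33.34, after rescaling. Cytoplasmic ribosomal RNA genes were also lowest in replicate 2 (0.0318%, 0.0042% and 0.0213% of counts in replicates 1, 2 and 3), so the ratios can follow depletion, and carryover and a difference in mitochondrial transcripts cannot be told apart.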
